A study of Homo sapiens with 118 samples.

How the data were processed

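Per the file headers, each array was an Agilent 4x44k slide position read with Feature Extraction 10.7.3.1 (10.7 per the labels) under protocol GE2_107_Sep09. The scanner files were deposited with spot and background signals as intensity and a LogRatio in log10 of Cy5 over Cy3. The deposited series matrix holds log10 ratios of Cy3 over Cy5: each value equals minus the LogRatio of the same spot within 5e-06 and is not centred further, so its scale, centring and direction are known. Its column medians lay between -0.0121 and 0 in WS8, between -0.00833 and 0.00383 in 5C and at 0 in 2A. Per the labels, Cy3 held estradiol-treated RNA and Cy5 the time-matched vehicle pool on all arrays. Values were tested as log2, computed from the deposited intensities.

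Mean spot signals were corrected for median local background (normexp, offset 50) and normalised within each array by loess, with control spots at weight 0. Spots marked as outliers (0.687% of spots) were left out, and no spot was saturated. Of 45015 spots per array, 43376 were not controls and held 41000 probes. The 37954 probes well above background on at least 50% of the arrays of a group in either channel were kept, and the brightest probe stood for each of 28057 gene names, of which 17783 were official symbols. Of the probes, 26222 were named by accession, 235 by a list of accessions, 1982 by symbol and 513 by synonym, and 12048 kept the name of the file. Where a gene had several probes they could disagree: of 61 called named values of the lines with several probes, 25 had a probe short of 1.5-fold.

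All 21 groups of line and time were fitted together in limma as group means, and each group mean was tested against 0. The lines were compared at 6, 24 and 96 h and the 7 times of a line by the F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1.5-fold (for time courses, between some pair of times). The 25 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. Of 450 list tests 141 were called by camera, of which 73 held with an estimated correlation and 141 with fry. The lists were estrogen-induced and estrogen-repressed genes, DNA replication, mitosis, CDK inhibitors, PERK/ATF4 response, ATF6/XBP1 response, pro-apoptotic BCL2 family, anti-apoptotic genes, caspases, death receptors and TNF family, NF-kappaB, interferon-stimulated genes, NRF2, p53 targets, cholesterol synthesis, lipid genes, hypoxia and glycolysis, MYC and ribosome biogenesis, heat shock, immediate early genes, and luminal, basal, fibroblast and leukocyte markers. The design, the lists, the naming rule and the alternatives (except those said to be later) were fixed before the data were examined.

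By the naming rule, the 4 highest and 4 lowest called genes with an official symbol and the same sign on every array were named per line at 6, 24 and 96 h. For differences between lines the arrays of both lines were not to overlap. For time courses the 4 genes with the largest F were named, and for lists the members with the largest changes. TFF1, PGR, GREB1, ESR1, BCL2, BCL2L11, CASP4, DDIT3 and HSPA5 were always given. The version of the rule over genes with a value on every array was chosen after the values were seen, because some of the lowest genes of 2A rested on 1 to 3 arrays. Where a probe was not well above background on any array of a group in 1 channel, its fold is a bound ("at least"), and a difference with such a group was given no value. The bound sets the mean of the brighter channel against the mean, per array, of the higher of the dim spot and the lowest signal among probes well above background, after loess and Aquantile, and is open to dye bias.

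The number of arrays per group, 4 to 6, limits the precision. Median centring in place of loess moved the median of all genes by -0.11, -0.12, -0.20, -0.20, -0.23, -0.11 and -0.06 in WS8 over the 7 times, by -0.14, -0.10, -0.09, -0.13, -0.08, -0.14 and -0.20 in 5C and by 0.04, 0.00, 0.05, -0.03, 0.00, 0.14 and -0.08 in 2A, and every change is relative to the main scale. On simulated data, run after the arrays, the fit recovered 100% of 100 genes shifted by log2 1 and of 100 shifted by log2 2. It called 0 unchanged genes and found the 1 shifted list of 25. This speaks for simulated noise only, not for the blocked or weighted fits. The block, slide, scan day and array weight fits used a matrix with missing values filled, their 0 variances were offset, and the array weights gave a convergence warning. Lists under alternatives were tested with cameraPR. Tools were R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the package data.table (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9.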

Results

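Messenger RNA of 3 derivatives of the MCF-7 breast cancer line was measured on arrays of 2 colours after estradiol or ethanol vehicle. MCF-7:WS8 (WS8) depends on estrogen and had been without it for 3 days. MCF-7:5C (5C) and MCF-7:2A (2A) were kept in medium free of estrogen. Each array set RNA of 1 plate treated with 1e-09 M estradiol (Cy3) against a pool of vehicle-treated RNA of the same line and time (Cy5). Times were 2, 6, 12 and 24 h, then 48, 72 and 96 h. There were 40 arrays of WS8, 38 of 5C and 40 of 2A. WS8 had 5 arrays at 2 h and at 6 h, 5C had 4 at 12 h and at 48 h, and 2A had 4 at 2 h. Every other group had 6. A positive log2 ratio is higher expression with estradiol.

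In Cy3, 50.01% to 83.0% of probes per WS8 array were well above background, 53.4% to 93.1% in 5C and 63.6% to 71.9% in 2A. In Cy5 the shares were 54.4% to 88.7%, 59.2% to 96.7% and 53.2% to 69.0%. Arrays of the same group correlated over genes between 0.406 and 0.974. WS8 and 5C were read on scanner G2505B and 2A on G2505C, and no slide held more than 1 line, so line and slide or scan batch cannot be told apart. All arrays ran in 1 dye orientation, so gene-specific dye bias stays in every ratio against 0 and cancels between times or lines only where their slides share it. Each group has 1 vehicle pool, which is 1 control sample shared by all its arrays. The tests of a ratio against 0, between lines and between times therefore all leave out the spread between pools. So does the SE of a difference.

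The 9 genes followed in every line lie as follows in build hg18, by the probe used, and are all protein-coding. TFF1 is on chromosome 21 from 42655482 to 42655541, PGR on 11 from 100406068 to 100406127 and GREB1 on 2 from 11700131 to 11700190. ESR1 is on chromosome 6 from 152465601 to 152465660, BCL2 on 18 from 59136115 to 59136150 and BCL2L11 on 2 from 111642363 to 111642422. CASP4 is on chromosome 11 from 104318839 to 104318898, DDIT3 on 12 from 56197467 to 56197793 and HSPA5 on 9 from 127039245 to 127040290. Gene values are mean log2 ratios ± SD over the arrays of a group, differences between lines are given ± SE of the fit, and list means carry the SD (or, for differences, the SE) of the array means. Square brackets hold the log2 ratio of another probe of the same gene that was short of 1.5-fold in that direction. After a word stands a value that ended the call or turned the sign: the mean of the probes (probes), median centring (median), or the value less the 2 h mean or, between lines, the 2 h difference (2 h). A list was called as a whole, and the members that passed are counted. Every gene picked by the naming rule had the same sign on all its arrays. Counts of list members passing the test over all genes were the same when adjusted over the list alone for all 141 called lists.

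The WS8 arrays ask how estrogen-dependent cells answer estradiol over 96 h. At 6 h, MYC, a transcription factor of growth, rose by 3.24 ± 0.29 [0.06; 2 h: -0.265] (n = 5), EGR3, an immediate early transcription factor, by 3.14 ± 1.15, GREB1, a cofactor of the estrogen receptor, by 2.81 ± 0.61 and the retinoic acid receptor RARA by 2.41 ± 0.56 [0.09; 2 h: 0.38]. The stem cell factor SOX2 (-1.88 ± 0.28), the G protein-coupled estrogen receptor GPER1 (-1.61 ± 0.20), the kinase anchor AKAP9 (-1.56 ± 0.21) and the Wnt ligand WNT11 (-1.43 ± 0.09 [-0.26]) fell. The secreted peptide TFF1, a classical estrogen target, rose by 1.95 ± 0.16, while PGR, the progesterone receptor, measured 0.02 ± 0.04. Genes of the estrogen-induced list rose, 32 of 35 members higher and 1 lower (list mean 1.22 ± 0.30, adjusted p = 3.93e-48). Ribosome biogenesis genes rose, 19 of 27 members higher (list mean 0.73 ± 0.11, adjusted p = 3.60e-39). Immediate early genes were called higher, 5 of 20 members higher (list mean 0.24 ± 0.11, adjusted p = 0.00183, adjusted p = 0.297 with an estimated correlation, 0.0588 with median centring and 0.243 less the 2 h mean). The estrogen-repressed list was lower, 1 of 25 members higher and 7 lower (list mean -0.38 ± 0.06, adjusted p = 2.67e-07). Mitosis genes were lower, 10 of 32 members lower (list mean -0.39 ± 0.08, adjusted p = 2.91e-15). The NRF2 list was called lower, 1 of 21 members higher and 1 lower (list mean -0.12 ± 0.01, adjusted p = 0.0403, adjusted p = 0.110 with an estimated correlation and 0.181 with the Feature Extraction log ratio), although its member HMOX1, heme oxygenase, rose by 0.74 ± 0.17 [median: 0.11; 2 h: -0.43]. The 8 named genes had a largest adjusted p of 1.29e-22.

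At 24 h in WS8, GREB1 was up 16.8-fold (4.07 ± 0.33, n = 6), EGR3 16.7-fold (4.06 ± 0.11), TFF1 9.17-fold (3.20 ± 0.40) and the amino acid transporter SLC7A5 8.63-fold (3.11 ± 0.18). The protease inhibitor CSTA (-3.25 ± 0.03), the proton pump subunit ATP6V0A4 (-3.15 ± 0.21), WNT11 (-3.14 ± 0.09 [-0.56]) and SERHL2 (-2.95 ± 0.10) fell, and the 8 had a largest adjusted p of 4.42e-38. The chaperone HSPA5 rose by 0.96 ± 0.04 [0.13; probes: 0.54; median: 0.44] and ESR1, the estrogen receptor, fell (-1.30 ± 0.05 [0.25; probes: -0.34]). Estrogen-induced genes rose, 33 of 35 members higher (list mean 1.90 ± 0.04, adjusted p = 1.79e-34). Ribosome biogenesis genes rose, 23 of 27 members higher (list mean 0.97 ± 0.02, adjusted p = 1.02e-24). Heat shock genes were higher, 6 of 16 members higher and 1 lower (list mean 0.46 ± 0.02, adjusted p = 2.60e-04, adjusted p = 0.142 with an estimated correlation, list mean turned to -0.02 with median centring). DNA replication genes were higher, 5 of 37 members higher and 1 lower (list mean 0.16 ± 0.02, adjusted p = 0.0116, adjusted p = 0.578 with an estimated correlation, list mean turned to -0.33 with median centring). Genes of the ATF6/XBP1 response were higher, 8 of 31 members higher and 3 lower (list mean 0.22 ± 0.01, adjusted p = 0.0334, adjusted p = 0.339 with an estimated correlation, list mean turned to -0.24 with median centring), SDF2L1 rising by 2.17 ± 0.17 [2 h: 0.47] while SEL1L (-1.17 ± 0.05 [-0.34]) and HERPUD1 (-0.99 ± 0.06) fell. The estrogen-repressed list fell, 16 of 25 members lower (list mean -1.12 ± 0.02, adjusted p = 7.84e-12), PSCA most (-2.92 ± 0.08 [-0.04]). Luminal markers fell, 8 of 15 members lower (list mean -0.60 ± 0.03, adjusted p = 1.83e-04). CDK inhibitors were lower, 1 of 14 members higher and 6 lower (list mean -0.45 ± 0.02, adjusted p = 0.0165, adjusted p = 0.0614 with an estimated correlation). CDKN1B, which restrains entry into S phase, measured -1.62 ± 0.08 [-0.17]. Anti-apoptotic genes were lower, 3 of 13 members lower (list mean -0.30 ± 0.01, adjusted p = 0.0236). The interferon-stimulated list was called lower, 1 of 38 members higher and 6 lower (list mean -0.20 ± 0.02, adjusted p = 0.0340, adjusted p = 0.282 with an estimated correlation and 0.124 with median centring).

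At 96 h in WS8, the scaffold protein gene PDZK1 was up 42.6-fold (5.41 ± 0.17, n = 6), GREB1 29.7-fold (4.89 ± 0.24), the growth factor AREG 25.0-fold (4.65 ± 0.28) and the noncoding RNA LINC00052 24.6-fold (4.62 ± 0.12). CSTA (-4.59 ± 0.14), the myelin protein gene PMP22 (-4.48 ± 0.11), WNT11 (-4.46 ± 0.12) and the adhesion molecule CEACAM6 (-3.94 ± 0.12) fell, and the 8 had a largest adjusted p of 4.61e-45. PGR rose by 2.92 ± 0.14, with its vehicle channel well above background on 1 of 6 arrays. Replication genes rose, 21 of 37 members higher (list mean 0.69 ± 0.08, adjusted p = 3.36e-15). CDC6 measured 1.25 ± 0.17 and RFC4 1.22 ± 0.06. Mitosis genes rose, 22 of 32 members higher (list mean 0.73 ± 0.06, adjusted p = 9.66e-15). The estrogen-induced list rose, 33 of 35 members higher (list mean 2.20 ± 0.05, adjusted p = 5.90e-29). Ribosome biogenesis genes rose, 18 of 27 members higher (list mean 0.75 ± 0.06, adjusted p = 1.69e-14). Genes of the PERK/ATF4 stress response were higher, 12 of 22 members higher and 1 lower (list mean 0.92 ± 0.35, adjusted p = 2.20e-07, adjusted p = 0.147 with an estimated correlation). The cystine transporter SLC7A11 measured 2.69 ± 0.47, the serine synthesis enzyme PSAT1 2.29 ± 0.44 and DDIT3, encoding CHOP, 0.69 ± 0.63. Heat shock genes were higher, 9 of 16 members higher and 1 lower (list mean 0.53 ± 0.07, adjusted p = 3.57e-04, adjusted p = 0.129 with an estimated correlation). HSPA5 rose by 0.95 ± 0.12 [-0.25; probes: 0.35]. Cholesterol synthesis genes were higher, 10 of 23 members higher (list mean 0.46 ± 0.15, adjusted p = 9.13e-05, adjusted p = 0.129 with an estimated correlation). Lipid genes were higher, 8 of 19 members higher and 3 lower (list mean 0.48 ± 0.06, adjusted p = 0.00757). Basal markers were higher, 8 of 17 members higher and 1 lower (list mean 0.53 ± 0.03, adjusted p = 8.32e-04). Luminal markers fell, 11 of 15 members lower (list mean -1.10 ± 0.04, adjusted p = 1.62e-08), with SPDEF at -2.29 ± 0.07 and ESR1 at -1.73 ± 0.11 [0.05]. The estrogen-repressed list fell, 17 of 25 members lower (list mean -1.25 ± 0.09, adjusted p = 2.35e-10). BCL2L11, encoding the death protein BIM, rose by 0.86 ± 0.18 [0.39].

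In WS8, 835, 673, 1868, 1710, 1975, 2240 and 2612 genes were higher and 101, 385, 1598, 2357, 2703, 2583 and 2653 lower over the 7 times, of 28057 tested, but less the 2 h mean 305 and 875 were higher and 304 and 1035 lower at 6 and 12 h. With median centring in place of loess, 187, 138, 615, 556, 740, 1487 and 2156 were higher and 2856, 4303, 7187, 6061, 5785, 3625 and 3144 lower, and the Feature Extraction log ratio gave 1759 higher and 1131 lower at 2 h and 1680 and 1586 at 6 h.

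The 5C arrays ask the same of a line that resists estrogen deprivation. At 6 h in 5C, EGR3 rose by 4.11 ± 0.06 (n = 6), the sulfotransferase CHST8 by 2.25 ± 0.05, the retinal reductase DHRS3 by 2.22 ± 0.33 and the forkhead factor FOXC1 by 2.18 ± 0.13 [2 h: -0.92]. GPER1 (-2.23 ± 0.25), HMOX1 (-1.93 ± 0.27), the differentiation inhibitor ID2 (-1.90 ± 0.15 [2 h: -0.20]) and the epithelial factor GRHL3 (-1.75 ± 0.11 [2 h: -0.54]) fell, with a largest adjusted p of 3.23e-26 for all 8. TFF1 rose by 0.87 ± 0.28 [median: 0.055] and GREB1 by 2.18 ± 0.21 [0.52]. PGR measured 0.09 ± 0.15. The estrogen-induced list rose, 28 of 35 members higher (list mean 1.09 ± 0.07, adjusted p = 9.24e-33). Ribosome biogenesis genes were higher, 15 of 27 members higher (list mean 0.46 ± 0.03, adjusted p = 6.01e-17, adjusted p = 0.150 with median centring). Immediate early genes were called higher, 3 of 20 members higher (list mean 0.40 ± 0.12, adjusted p = 5.62e-06, adjusted p = 0.105 with an estimated correlation). FOS measured 1.82 ± 0.19 [2 h: -0.06]. Estrogen-repressed genes were lower, 4 of 25 members lower (list mean -0.30 ± 0.03, adjusted p = 0.00186, adjusted p = 0.208 with an estimated correlation).

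At 24 h in 5C, EGR3 was up 17.0-fold (4.09 ± 0.30, n = 6), TFF1 8.85-fold (3.15 ± 0.38), the collagen gene COL27A1 8.43-fold (3.08 ± 0.07 [0.54]) and GREB1 8.11-fold (3.02 ± 0.52). ID2 (-3.27 ± 0.24), GPER1 (-3.24 ± 0.32), the matrix protein gene EFEMP1 (-2.89 ± 0.10) and the membrane protein gene TM4SF1 (-2.79 ± 0.24) fell, with a largest adjusted p of 6.7e-28 for all 8. Interferon-stimulated genes fell, 1 of 38 members higher and 21 lower (list mean -0.63 ± 0.04, adjusted p = 6.21e-21). IFIT1 measured -1.47 ± 0.17, OAS3 -1.35 ± 0.06 and PSMB9 -1.34 ± 0.18, while the exonuclease ISG20 rose by 1.27 ± 0.07. The estrogen-induced list rose, 27 of 35 members higher (list mean 1.30 ± 0.10, adjusted p = 3.05e-33). The estrogen-repressed list was lower, 12 of 25 members lower (list mean -0.87 ± 0.07, adjusted p = 2.74e-14). BAMBI, a decoy receptor of TGF-beta signalling, measured -2.37 ± 0.12. Ribosome biogenesis genes were higher, 17 of 27 members higher (list mean 0.66 ± 0.02, adjusted p = 2.67e-22, adjusted p = 0.130 with median centring). Luminal markers fell, 8 of 15 members lower (list mean -0.62 ± 0.05, adjusted p = 6.33e-07). FOXA1 measured -1.55 ± 0.16 and ESR1 -1.23 ± 0.06 [0.07; probes: -0.38]. CDK inhibitors fell, 1 of 14 members higher and 7 lower (list mean -0.33 ± 0.05, adjusted p = 0.0106), although GADD45B rose by 0.98 ± 0.08 [median: 0.40; 2 h: 0.04]. Heat shock genes were higher, 3 of 16 members higher (list mean 0.36 ± 0.11, adjusted p = 4.20e-05, adjusted p = 0.0789 with an estimated correlation, list mean turned to -0.24 with median centring). BCL2L11 measured 0.38 ± 0.06 and CASP4, an inflammatory caspase, 0.53 ± 0.09, both under 1.5-fold.

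At 96 h in 5C, the protease gene PRSS23 was up 34.9-fold (5.12 ± 0.76, n = 6), the LIM protein gene FHL2 33.7-fold (5.07 ± 0.23), PDZK1 22.2-fold (4.47 ± 0.74) and GREB1 21.6-fold (4.44 ± 0.78). BAMBI (-3.90 ± 0.13), the chemokine receptor CXCR4 (-3.76 ± 0.09), TM4SF1 (-3.73 ± 0.11) and EFEMP1 (-3.62 ± 0.27) fell, with a largest adjusted p of 3.37e-41 for all 8. Interferon-stimulated genes were higher, 18 of 38 members higher (list mean 0.67 ± 0.04, adjusted p = 1.07e-12, list mean turned to -0.11 with median centring). MX2 measured 1.74 ± 0.29 and IRF1 1.65 ± 0.39. Pro-apoptotic BCL2 family genes were higher, 8 of 15 members higher and 1 lower (list mean 0.69 ± 0.09, adjusted p = 0.00258, adjusted p = 0.579 with median centring and 0.128 less the 2 h mean). BCL2L11 measured 2.04 ± 0.18 (its 4 probes between 0.71 and 2.33) and BBC3, BAX and HRK 2.21 ± 0.42 [0.50; 2 h: 0.63], 1.69 ± 0.39 and 1.98 ± 0.51. These last 3 also stood at 1.59, 1.06 and 1.06 at 2 h. Caspase genes were higher, 6 of 16 members higher and 1 lower (list mean 0.34 ± 0.10, adjusted p = 0.0322, adjusted p = 0.0992 with the Feature Extraction log ratio and 0.146 less the 2 h mean, list mean turned to -0.17 with median centring). CASP4 measured 1.60 ± 0.19, CASP1 1.003 ± 0.45 and CASP8 0.95 ± 0.20 [0.14; median: 0.30], while CASP9, the initiator caspase of the mitochondrial pathway, fell (-1.12 ± 0.24).

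Death receptor and TNF family genes were higher at 96 h in 5C, 7 of 23 members higher and 1 lower (list mean 0.63 ± 0.14, adjusted p = 0.00204, adjusted p = 0.119 with median centring). Lymphotoxin beta, LTB, measured 3.86 ± 0.52 and TNF 2.65 ± 0.69. NF-kappaB and inflammatory genes were higher, 12 of 27 members higher (list mean 0.72 ± 0.14, adjusted p = 5.07e-07). IL4R measured 3.55 ± 0.34 and RELB 2.29 ± 0.20. Hypoxia and glycolysis genes were higher, 14 of 24 members higher and 1 lower (list mean 0.76 ± 0.13, adjusted p = 2.30e-08, adjusted p = 0.172 with median centring). Adrenomedullin, ADM, measured 2.45 ± 0.47 and VEGFA 1.75 ± 0.65 [0.29]. Basal markers were higher, 6 of 17 members higher and 1 lower (list mean 0.57 ± 0.15, adjusted p = 0.00204). LAMB3 measured 2.39 ± 0.38 and TP63 4.23 ± 0.94 [0.36], a gene that the death receptor and TNF family list holds too. The estrogen-induced list rose, 24 of 35 members higher and 1 lower (list mean 1.26 ± 0.19, adjusted p = 3.01e-14). FOS measured 3.99 ± 0.37 and TFF1 3.71 ± 0.33. PGR measured 0.39 ± 0.24, under 1.5-fold. Estrogen-repressed genes were lower, 1 of 25 members higher and 9 lower (list mean -0.72 ± 0.12, adjusted p = 1.63e-04, adjusted p = 0.0525 with an estimated correlation). Luminal markers fell, 9 of 15 members lower (list mean -1.004 ± 0.12, adjusted p = 9.77e-09). SPDEF measured -2.50 ± 0.17 and ESR1 -2.39 ± 0.29 [-0.12]. Ribosome biogenesis genes were higher, 8 of 27 members higher (list mean 0.34 ± 0.07, adjusted p = 0.00106, adjusted p = 0.0718 with an estimated correlation and 0.156 less the 2 h mean, list mean turned to -0.42 with median centring). Heat shock genes were called higher, 4 of 16 members higher (list mean 0.25 ± 0.03, adjusted p = 0.0252, adjusted p = 0.324 with an estimated correlation, list mean turned to -0.56 with median centring). HSPA5 measured 0.02 ± 0.16 [median: -0.78] and DDIT3 0.38 ± 0.19, both under 1.5-fold. Of the 6 arrays, 1 stood apart in the spread of its ratios, and without the 8 such arrays of the series 5166 genes were called at 96 h.

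In 5C, 1281, 735, 613, 966, 928, 1973 and 2414 genes were higher and 396, 525, 600, 1291, 1498, 2035 and 2155 lower from 2 h to 96 h, but less the 2 h mean 139 and 668 were higher and 249 and 1367 lower at 6 and 12 h. With median centring, 1266, 382, 316, 819, 551, 1143 and 1895 were higher and 5303, 3117, 1606, 5541, 2677, 4863 and 7653 lower, and the Feature Extraction log ratio gave 1812 and 1061 at 2 h.

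The 2A arrays ask the same of the other resistant line. At 6 h in 2A, EGR3 rose by 3.42 ± 0.78 (n = 6), MYC by 2.43 ± 0.29 [0.10; 2 h: 0.19], the receptor kinase RET by 2.26 ± 0.24 [2 h: 0.43] and the neurofilament gene NEFH by 2.21 ± 0.70. PGR rose by 2.00 ± 0.50 and GREB1 by 2.17 ± 0.82. TFF1 measured 0.50 ± 0.23, under 1.5-fold. The 4 lowest genes of the naming rule, ARL11, OR2W3, MORN5 and APOC2, each had a usable spot on 1 array, the rest being marked as outliers, where estradiol was at least 42.9-fold, 29.4-fold, 30.3-fold and 35.1-fold lower, but less the 2 h mean they stood at -0.77, -0.58, -0.46 and -0.04, and another ARL11 probe at -0.01. Over genes with a value on every array, a rule chosen after the values were seen, the lowest were PRR15 (-1.83 ± 0.39 [-0.56]), the cytoskeletal linker EPPK1 (-1.63 ± 0.27 [-0.45; 2 h: -0.52]), WTAP (-1.60 ± 0.36 [0.08; probes: -0.51; 2 h: -0.31]), which serves RNA methylation, and PDZD9 (at least 2.75-fold lower). The estrogen-induced list rose, 31 of 35 members higher (list mean 1.32 ± 0.21, adjusted p = 9.26e-39). Ribosome biogenesis genes were higher, 8 of 27 members higher (list mean 0.43 ± 0.07, adjusted p = 1.42e-13). Immediate early genes were called higher, 4 of 20 members higher and 1 lower (list mean 0.25 ± 0.12, adjusted p = 0.0142, adjusted p = 0.607 with an estimated correlation). FOS measured 1.40 ± 0.40 [2 h: -0.27], while JUNB fell (-0.79 ± 0.15 [-0.18; probes: -0.48; 2 h: 0.25]). Estrogen-repressed genes were lower, 9 of 25 members lower (list mean -0.47 ± 0.08, adjusted p = 3.14e-07). CASP4 fell on its brighter probe (-0.59 ± 0.59 [0.02; probes: -0.285; median: -0.52; 2 h: -0.18]) and stood at 0.02 on the other.

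At 24 h in 2A, PDZK1 was up 17.1-fold (4.09 ± 0.19, n = 6), EGR3 10.998-fold (3.46 ± 0.17) and NEFH 7.32-fold (2.87 ± 0.20), and the epidermal calcium-binding protein gene S100A7 was at least 8.90-fold higher, its vehicle channel not well above background on any array. PGR rose by 2.52 ± 0.17 and TFF1 by 1.28 ± 0.14. Of the 4 lowest by rule, ARL11 (at least 18.7-fold lower) and CNGB1 (-4.68 [0.09; probes: -0.30]) rested on 1 array, C4orf36 (-4.51) on 2 and APOC2 (at least 21.7-fold lower) on 3, with ARL11 at 0.07 and APOC2 at 0.63 less the 2 h mean. Among genes with a value on every array the lowest were ATP6V0A4 (-3.02 ± 0.17), PSCA (-3.00 ± 0.12 [0.05]), RPRM (-2.96 ± 0.26), whose product arrests the cell cycle, and CXCR4 (-2.79 ± 0.39). Estrogen-induced genes rose, 28 of 35 members higher (list mean 1.35 ± 0.08, adjusted p = 3.96e-22). Estrogen-repressed genes fell, 16 of 25 members lower (list mean -1.05 ± 0.11, adjusted p = 3.02e-11). Mitosis genes were higher, 6 of 32 members higher and 1 lower (list mean 0.30 ± 0.08, adjusted p = 9.57e-05, adjusted p = 0.303 with an estimated correlation). The checkpoint kinase BUB1B measured 1.47 ± 0.14 and MKI67 0.94 ± 0.25. Ribosome biogenesis genes rose, 14 of 27 members higher (list mean 0.58 ± 0.04, adjusted p = 2.76e-12). PERK/ATF4 response genes were higher, 4 of 22 members higher (list mean 0.43 ± 0.41, adjusted p = 5.70e-04, adjusted p = 0.458 with an estimated correlation). SLC7A11 measured 1.92 ± 0.56 [0.32] and DDIT3 0.88 ± 0.84. Heat shock genes were higher, 7 of 16 members higher (list mean 0.41 ± 0.08, adjusted p = 5.70e-04, adjusted p = 0.240 with an estimated correlation and 0.135 with median centring). HSPA5 rose by 0.66 ± 0.30 [0.11; probes: 0.38]. Cholesterol synthesis genes were called higher, 5 of 23 members higher and 2 lower (list mean 0.20 ± 0.07, adjusted p = 0.0302, adjusted p = 0.458 with an estimated correlation, 0.163 with median centring and 0.0638 with the Feature Extraction log ratio), with FDFT1 at 1.41 ± 0.13 and SC5D at -0.85 ± 0.10 [0.01; probes: -0.52], and hypoxia and glycolysis genes, 3 of 24 members higher and 2 lower (list mean 0.17 ± 0.02, adjusted p = 0.0415, adjusted p = 0.240 with an estimated correlation, 0.294 with median centring and 0.203 less the 2 h mean). Luminal markers were lower, 5 of 15 members lower (list mean -0.39 ± 0.05, adjusted p = 0.00786, adjusted p = 0.193 with an estimated correlation). ESR1 measured -1.14 ± 0.11 [0.29; probes: -0.47].

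At 96 h in 2A, S100A7 was up 46.8-fold (5.55 ± 0.21, n = 6), S100A8 32.7-fold (5.03 ± 0.13), SPRR3 25.1-fold (4.65 ± 0.23) and keratin KRT6B 21.6-fold (4.43 ± 0.18). Basal markers rose, 10 of 17 members higher (list mean 1.05 ± 0.06, adjusted p = 8.25e-10). KRT6A measured 3.28 ± 0.15, KRT17 2.99 ± 0.16 and LAMB3 2.12 ± 0.20. BAMBI fell (-4.32 ± 0.12), while DOCK4 (at least 34.5-fold lower), STK32B (at least 21.5-fold lower) and LINC01144 (-5.07 [2 h: -0.43]) rested on 1 array each, and the first 2 stood at -0.72 and -0.51 less the 2 h mean, and other probes of DOCK4 and STK32B lay near 0. Among genes with a value on every array CXCR4 (-3.70 ± 0.09), CEACAM6 (-3.27 ± 0.15) and GPER1 (-2.97 ± 0.29) followed BAMBI. The estrogen-induced list was higher, 19 of 35 members higher and 1 lower (list mean 0.94 ± 0.03, adjusted p = 4.52e-10, adjusted p = 0.925 less the 2 h mean), with AREG at 3.96 ± 0.19. Estrogen-repressed genes were lower, 3 of 25 members higher and 12 lower (list mean -0.68 ± 0.07, adjusted p = 0.00202, adjusted p = 0.151 with an estimated correlation). Immediate early and MAPK feedback genes were higher, 9 of 20 members higher (list mean 0.59 ± 0.09, adjusted p = 1.41e-04, adjusted p = 0.108 with an estimated correlation). ETV5 measured 2.41 ± 0.32 and the phosphatase DUSP6 2.02 ± 0.19. NRF2 targets were higher, 10 of 21 members higher and 1 lower (list mean 0.48 ± 0.04, adjusted p = 2.48e-04). Targets of p53 were higher, 7 of 19 members higher and 2 lower (list mean 0.28 ± 0.05, adjusted p = 0.00471, adjusted p = 0.0566 with an estimated correlation and 0.220 with median centring). CDKN1A measured 1.32 ± 0.06 and GDF15 1.36 ± 0.26 [2 h: 0.51], while PLK2 fell (-1.40 ± 0.12 [2 h: -0.55]). Hypoxia and glycolysis genes were higher, 9 of 24 members higher (list mean 0.53 ± 0.05, adjusted p = 1.26e-07). Cholesterol genes were higher, 8 of 23 members higher and 2 lower (list mean 0.39 ± 0.12, adjusted p = 5.30e-04, adjusted p = 0.167 with an estimated correlation), with INSIG1 at 1.42 ± 0.13. Lipid genes were higher, 7 of 19 members higher and 1 lower (list mean 0.36 ± 0.03, adjusted p = 0.00465). The ATF6/XBP1 list was higher, 8 of 31 members higher and 3 lower (list mean 0.20 ± 0.11, adjusted p = 0.0147, adjusted p = 0.229 with an estimated correlation, list mean turned to -0.02 with median centring). HSPA5 measured 1.03 ± 0.29 [0.10; probes: 0.56], while XBP1 fell (-1.08 ± 0.19 [-0.53]).

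NF-kappaB genes were called higher at 96 h in 2A, 3 of 27 members higher and 1 lower (list mean 0.22 ± 0.02, adjusted p = 0.0141, adjusted p = 0.164 with an estimated correlation), with IL4R at 1.62 ± 0.11, and heat shock genes, 3 of 16 members higher (list mean 0.30 ± 0.09, adjusted p = 0.0189, adjusted p = 0.334 with an estimated correlation and 0.621 with median centring). The mitosis list was higher, 2 of 32 members higher (list mean 0.16 ± 0.09, adjusted p = 0.0242, adjusted p = 0.533 with an estimated correlation and 0.290 less the 2 h mean, list mean turned to -0.01 with median centring). Luminal markers fell, 9 of 15 members lower (list mean -0.72 ± 0.03, adjusted p = 2.81e-06). ESR1 measured -2.73 ± 0.21 [-0.42]. BCL2L11 rose by 0.59 ± 0.17 [0.46; median: 0.43; 2 h: 0.48], its 4 probes between 0.46 and 2.43, and BCL2, an anti-apoptotic gene, measured 0.58 ± 0.13 on 1 probe and -1.15 on the other. In 2A, 243, 627, 1069, 1434, 1594, 1528 and 1655 genes were higher from 2 h to 96 h. Lower were 1076, 1310, 1642, 2696, 2806, 2352 and 2458, each with 165 to 205 of the outlier set below. Less the 2 h mean, 185 and 478 were higher and 123 and 469 lower at 6 and 12 h. With median centring, 587, 691, 1757, 1187, 1596, 3452 and 1023 were higher and 936, 1454, 1322, 3218, 3022, 1595 and 3521 lower, and the Feature Extraction log ratio gave 1150 and 2044 at 2 h.

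**Figure D1:**
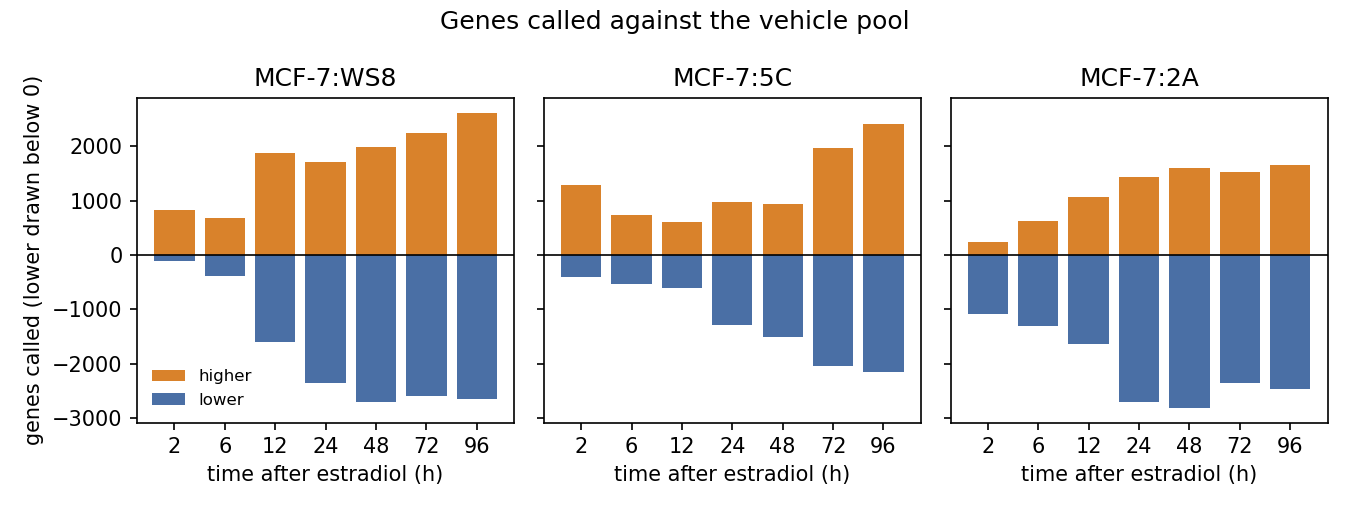
Genes called higher (upward) and lower (downward) with estradiol against vehicle, as numbers of genes on the y axis, by hours of treatment on the x axis for the 3 lines. WS8 went from 936 called genes at 2 h to 5265 at 96 h, 5C from 1677 to 4569 and 2A from 1319 to 4113.

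**Figure D2:**
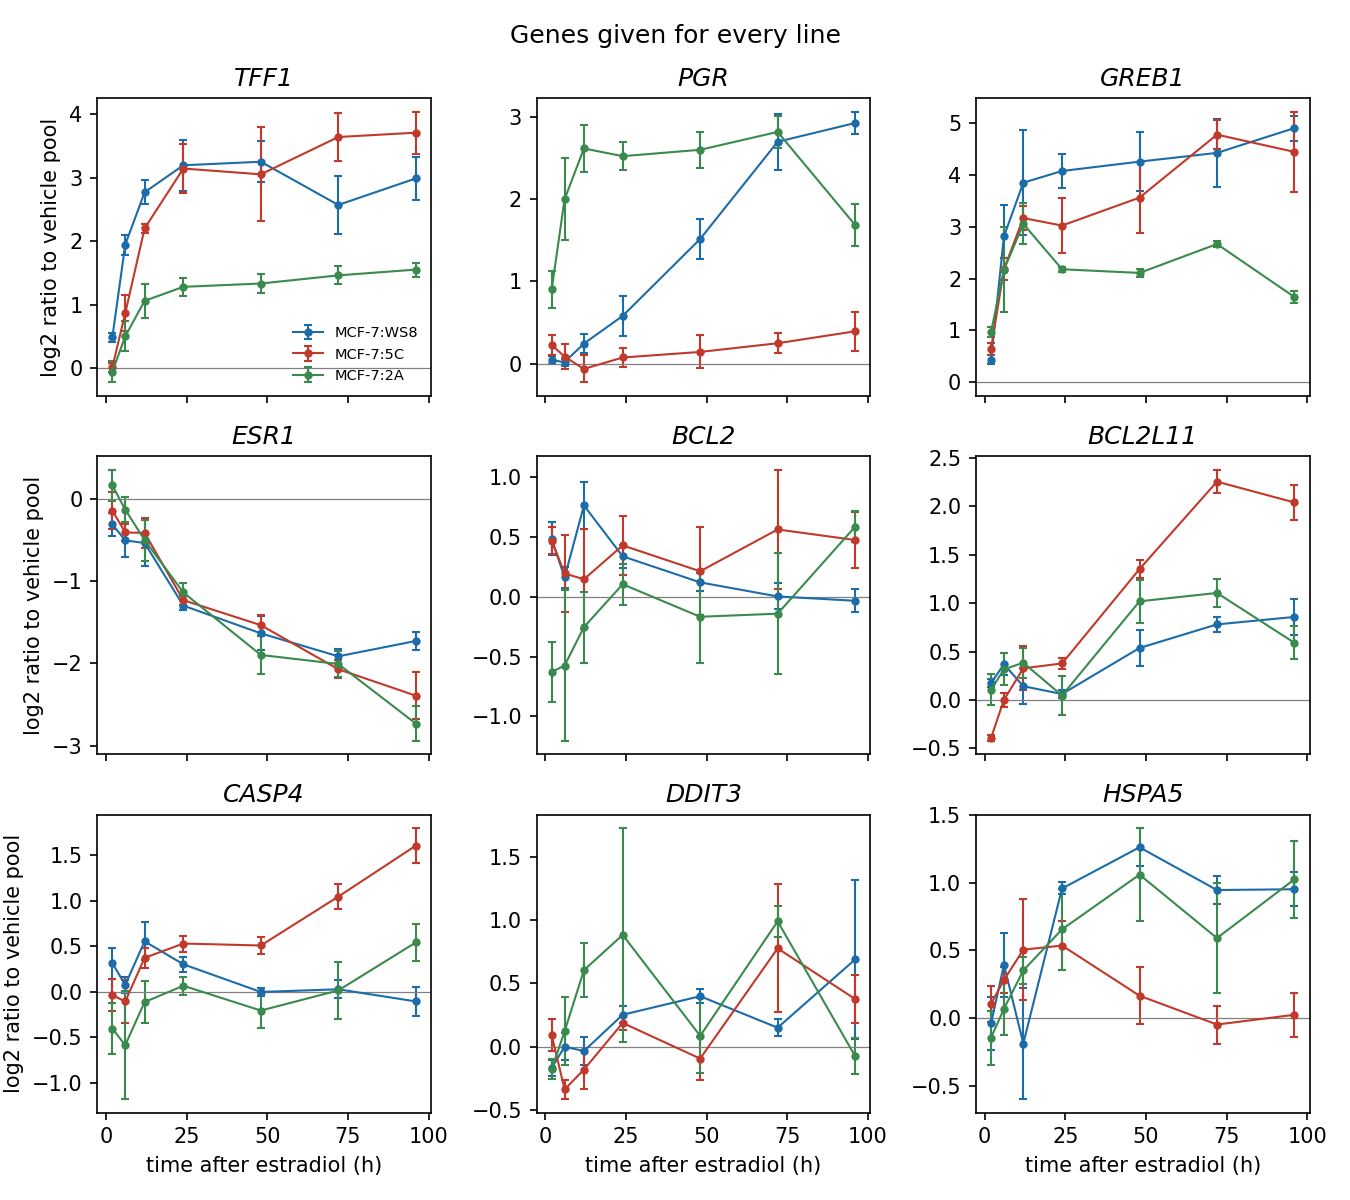
Log2 ratio of estradiol to vehicle (y axis) over hours of treatment (x axis) for the 9 genes followed in every line, as mean ± SD of 4 to 6 arrays for each of the 3 lines. At 96 h PGR reached 2.92 in WS8, 1.68 in 2A and 0.39 in 5C, and BCL2L11 reached 2.04 in 5C.

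Genes called in the same direction ask how much of the response lines share. At 24 h, 5C and WS8 shared 596 genes called higher where independent lists give 58.9 and 887 called lower where they give 108. 2A and WS8 shared 671 (87.7 for independent lists) and 1070 (227), and 5C and 2A shared 398 (49.5) and 755 (124). Across genes, which are not independent replicates, Pearson's r of 5C with WS8 was 0.66 at 6 h, 0.71 at 24 h and 0.41 at 96 h. It was 0.31, 0.51 and 0.43 for 2A with WS8 and 0.36, 0.50 and 0.50 for 5C with 2A. Each line had its own vehicle pools, but a dye bias they share would add to an overlap. Less the 2 h means, 5C and WS8 shared 297 and 787 genes at 24 h, 2A and WS8 338 and 992, and 5C and 2A 164 and 564 (r = 0.24), while 141 were lower in 5C and higher in 2A where independent lists give 82.4.

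The difference between 5C and WS8 asks where responses differ. Between lines, higher and lower refer to ratios, not levels. At 6 h, DHRS3 (1.63 ± 0.14), the peroxisomal oxidase ACOX2 (1.495 ± 0.13), CXXC5 (1.46 ± 0.14) and PGLYRP2 (1.46 ± 0.19 [2 h: 0.62]) were higher in 5C, while HMOX1 (-2.66 ± 0.19 [2 h: -0.58]), the chaperone cofactor SDF2L1 (-1.99 ± 0.16 [2 h: -0.02]), PPM1K (-1.74 ± 0.13 [0.00]) and STC2 (-1.40 ± 0.19 [-0.40; 2 h: -0.81]) were lower (6 and 5 arrays, a largest adjusted p of 2.49e-09). TFF1 was lower in 5C (-1.08 ± 0.17 [2 h: -0.61]). The mitosis list was higher, 2 of 32 members higher (list mean 0.28 ± 0.05, adjusted p = 2.93e-10, adjusted p = 0.125 with an estimated correlation), the ribosome biogenesis list lower, 2 of 27 members lower (list mean -0.26 ± 0.05, adjusted p = 6.74e-10), and the luminal list higher, 1 of 15 members higher and 1 lower (list mean 0.14 ± 0.02, adjusted p = 0.0315, adjusted p = 0.340 with an estimated correlation, 0.103 with median centring and 0.278 less the 2 h difference). At 24 h, WNT11 (2.78 ± 0.07), the netrin NTN4 (2.46 ± 0.10), PSCA (2.44 ± 0.11 [0.11]) and the cell cycle kinase CDK6 (2.40 ± 0.07) were higher in 5C, all of which had fallen in WS8. The phosphatase PPM1K (-2.97 ± 0.12 [-0.17]), AREG (-2.26 ± 0.15), the insulin-like growth factor binder IGFBP4 (-2.24 ± 0.16) and TMED9 (-2.21 ± 0.24) were lower (6 and 6 arrays, a largest adjusted p of 1.94e-13). Interferon-stimulated genes were lower in 5C, 1 of 38 members higher and 14 lower (list mean -0.43 ± 0.02, adjusted p = 7.62e-13). IFIT1 measured -1.29 ± 0.08. The ribosome biogenesis list was lower, 4 of 27 members lower (list mean -0.31 ± 0.01, adjusted p = 6.75e-09), and the estrogen-induced list lower, 2 of 35 members higher and 16 lower (list mean -0.60 ± 0.04, adjusted p = 2.85e-11, adjusted p = 0.0570 with an estimated correlation). Cholesterol synthesis genes were lower, 7 of 23 members lower (list mean -0.30 ± 0.01, adjusted p = 2.65e-05, adjusted p = 0.191 with an estimated correlation), as were replication genes, 4 of 37 members lower (list mean -0.18 ± 0.01, adjusted p = 9.73e-04, adjusted p = 0.556 with an estimated correlation), and mitosis genes, 2 of 32 members lower (list mean -0.14 ± 0.03, adjusted p = 0.0329, adjusted p = 0.614 with an estimated correlation and 0.0786 with the Feature Extraction log ratio).

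At 96 h, C11orf96 (4.93 ± 0.15), WNT11 (4.63 ± 0.07), the nuclear RNA MALAT1 (4.38 ± 0.35, its 5 probes between 1.23 and 4.38) and PMP22 (4.35 ± 0.06) were higher in 5C than in WS8. S100A8 (-4.48 ± 0.11), LINC00052 (a bound in 5C), the sphingolipid enzyme subunit SPTSSB (-3.59 ± 0.17) and the transcription factor MYB (-3.55 ± 0.07) were lower, with a largest adjusted p of 2.48e-21 over these 8. Interferon-stimulated genes were higher in 5C, 23 of 38 members higher (list mean 0.91 ± 0.02, adjusted p = 8.00e-14, adjusted p = 0.117 with median centring). IFI6 measured 2.43 ± 0.10 and OASL 2.36 ± 0.07. NF-kappaB genes were higher, 12 of 27 members higher and 1 lower (list mean 0.82 ± 0.06, adjusted p = 7.04e-08). RELB measured 3.36 ± 0.09 and NFKBIA 2.87 ± 0.08. Pro-apoptotic genes were higher, 9 of 15 members higher and 1 lower (list mean 0.75 ± 0.04, adjusted p = 3.44e-04, adjusted p = 0.289 with median centring). BAK1 measured 1.59 ± 0.11 and BCL2L11 1.18 ± 0.08 [0.32; median: 0.41]. CASP4 was higher by 1.71 ± 0.12. Death receptor and TNF family genes were higher, 7 of 23 members higher and 1 lower (list mean 0.68 ± 0.06, adjusted p = 4.38e-04). Targets of p53 were higher, 7 of 19 members higher (list mean 0.60 ± 0.03, adjusted p = 0.00289, list mean turned to -0.05 with median centring). Hypoxia genes were higher, 12 of 24 members higher and 3 lower (list mean 0.67 ± 0.06, adjusted p = 5.25e-05, adjusted p = 0.553 with median centring), with ADM at 3.53 ± 0.10, and CDK inhibitors, 7 of 14 members higher (list mean 0.59 ± 0.04, adjusted p = 0.00289, adjusted p = 0.772 with median centring). Estrogen-repressed genes were higher, 12 of 25 members higher and 4 lower (list mean 0.53 ± 0.06, adjusted p = 0.00483, adjusted p = 0.169 with an estimated correlation and 0.166 with the Feature Extraction log ratio), although EFEMP1 was lower by -3.10 ± 0.09. The leukocyte list, which marks cells foreign to these cultures, was higher, 2 of 12 members higher (list mean 0.34 ± 0.05, adjusted p = 0.0423, adjusted p = 0.240 with an estimated correlation and 0.0626 with the Feature Extraction log ratio), with CD68 at 1.14 ± 0.10.

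Replication genes were lower in 5C than in WS8 at 96 h, 23 of 37 members lower (list mean -0.80 ± 0.04, adjusted p = 3.77e-14), with RRM2 at -1.82 ± 0.12 [-0.20] and CCNE2 at -1.66 ± 0.15, and mitosis genes, 1 of 32 members higher and 15 lower (list mean -0.59 ± 0.04, adjusted p = 2.93e-08, adjusted p = 0.0578 with an estimated correlation). Ribosome biogenesis genes were lower, 1 of 27 members higher and 11 lower (list mean -0.41 ± 0.04, adjusted p = 3.07e-05). The estrogen-induced list was lower, 3 of 35 members higher and 23 lower (list mean -0.93 ± 0.08, adjusted p = 2.39e-08, adjusted p = 0.0535 with an estimated correlation). PGR measured -2.53 ± 0.13, while TFF1 was higher by 0.72 ± 0.17 [-0.03; probes: 0.345; median: -0.12] (0.46 with the Feature Extraction log ratio). PERK/ATF4 genes were lower, 5 of 22 members higher and 12 lower (list mean -0.61 ± 0.14, adjusted p = 0.00322, adjusted p = 0.413 with an estimated correlation), with ASNS at -2.46 ± 0.15 [0.31], as were cholesterol genes, 2 of 23 members higher and 8 lower (list mean -0.39 ± 0.06, adjusted p = 0.00745, adjusted p = 0.273 with an estimated correlation). SQLE measured -2.36 ± 0.11. HSPA5 was lower by -0.93 ± 0.13 [-0.35]. ESR1 was lower by -0.66 ± 0.10 [-0.16; probes: -0.34] and BCL2 stayed under 1.5-fold (0.51 ± 0.17 [probes: -0.65]). Between 5C and WS8, 257, 941 and 3274 genes were higher and 314, 937 and 3102 lower at 6, 24 and 96 h. Only 200 differed at 6 h less the 2 h difference. With median centring, 636 and 291 differed at 6 h and 1833 and 6924 at 96 h.

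The difference between 2A and WS8 asks the same. At 6 h, PGR (1.98 ± 0.13), PDZK1 (1.92 ± 0.20 [2 h: 0.92]), CXXC5 (1.33 ± 0.14) and the kinase SGK1 (1.27 ± 0.18 [2 h: -0.245]) were higher in 2A (6 and 5 arrays). ARL11, OR2W3, MORN5 and APOC2, bounds in 2A, were lowest by the fixed rule, and among genes with a value on every array LOC441722 (-2.13 ± 0.21 [2 h: 0.11]), the splicing factors SRSF6 (-2.06 ± 0.18 [2 h: -0.725]) and SRSF5 (-1.66 ± 0.12 [2 h: -0.05]) and SDF2L1 (-1.93 ± 0.16 [2 h: -0.07]) were. The mitosis list was higher, 6 of 32 members higher (list mean 0.29 ± 0.05, adjusted p = 2.60e-06, adjusted p = 0.428 with an estimated correlation), and the ribosome biogenesis list lower, 3 of 27 members lower (list mean -0.29 ± 0.06, adjusted p = 3.51e-06, adjusted p = 0.0641 with an estimated correlation, list mean turned to 0.12 with median centring). At 24 h, S100A7 (a bound in 2A), WNT11 (2.67 ± 0.07 [0.57]) and PDZK1 (2.02 ± 0.19, or 0.50 with the Feature Extraction log ratio) were higher in 2A, as was PGR (1.94 ± 0.13, but -0.37 with the Feature Extraction log ratio and the series matrix). Lowest over genes with a value on every array were SRSF6 (-2.92 ± 0.17), RARA (-2.44 ± 0.14 [-0.07]), MALAT1 (-2.42 ± 0.35 [0.80; probes: -0.57; 2 h: -0.51]) and the adenylate kinase AK4 (-2.32 ± 0.15), and by the fixed rule CNGB1 (-4.70 [0.04; probes: -0.34]) and C4orf36 (-4.38), on 1 and 2 arrays of 2A, and the bounds ARL11 and APOC2. TFF1 was lower in 2A by -1.92 ± 0.17 and GREB1 by -1.89 ± 0.27 [-0.12]. Estrogen-induced genes were lower, 2 of 35 members higher and 15 lower (list mean -0.55 ± 0.03, adjusted p = 1.21e-05, adjusted p = 0.283 with an estimated correlation and 0.0582 with median centring), as were ribosome biogenesis genes, 7 of 27 members lower (list mean -0.39 ± 0.02, adjusted p = 4.62e-06, adjusted p = 0.0543 with an estimated correlation and 0.567 with median centring). Mitosis genes were higher, 8 of 32 members higher and 1 lower (list mean 0.32 ± 0.04, adjusted p = 4.32e-04, adjusted p = 0.375 with an estimated correlation), and NRF2 genes, 5 of 21 members higher and 1 lower (list mean 0.30 ± 0.04, adjusted p = 0.00727, adjusted p = 0.0543 with an estimated correlation). The metallothionein MT2A measured 1.71 ± 0.10.

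At 96 h, WNT11 (4.67 ± 0.07) and KRT6B (3.34 ± 0.08) had higher ratios in 2A than WS8. So had CD24 (3.33 ± 0.14) and CSTA (3.32 ± 0.09, though -1.27 in 2A). The sulfatase SULF1 was lower (-4.44 ± 0.08), as were, over genes with a value on every array, MYB (-4.13 ± 0.07), the chemokine CXCL12 (-3.70 ± 0.16) and AK4 (-3.44 ± 0.15), and by the fixed rule LINC01144 (-4.92 [2 h: -0.24]), on 1 array of 2A, and the bounds DOCK4 and STK32B. Estrogen-induced genes were lower, 24 of 35 members lower (list mean -1.25 ± 0.03, adjusted p = 2.07e-13), with GREB1 at -3.25 ± 0.27 [-0.29], TFF1 at -1.44 ± 0.17 and PGR at -1.24 ± 0.13 [-0.36], and estrogen-repressed genes higher, 13 of 25 members higher and 4 lower (list mean 0.57 ± 0.05, adjusted p = 4.64e-04, adjusted p = 0.0822 with an estimated correlation). Replication genes were lower, 21 of 37 members lower (list mean -0.57 ± 0.08, adjusted p = 7.58e-10, adjusted p = 0.0611 with an estimated correlation), mitosis genes lower, 15 of 32 members lower (list mean -0.57 ± 0.05, adjusted p = 1.37e-08, adjusted p = 0.0805 with an estimated correlation), and ribosome biogenesis genes lower, 14 of 27 members lower (list mean -0.66 ± 0.02, adjusted p = 2.39e-10). PERK/ATF4 genes were lower, 11 of 22 members lower (list mean -0.83 ± 0.15, adjusted p = 2.01e-05, adjusted p = 0.186 with an estimated correlation). PSAT1 measured -2.53 ± 0.11 and DDIT3 -0.76 ± 0.17. Targets of p53 were higher, 12 of 19 members higher and 1 lower (list mean 0.70 ± 0.03, adjusted p = 3.16e-06), with GDF15 at 2.53 ± 0.15, and NRF2 targets, 8 of 21 members higher and 1 lower (list mean 0.59 ± 0.04, adjusted p = 5.96e-05). HMOX1 measured 2.90 ± 0.18 and NQO1 1.70 ± 0.08. Basal markers were higher, 9 of 17 members higher and 1 lower (list mean 0.52 ± 0.03, adjusted p = 7.92e-04), although TP63 was lower by -1.06 ± 0.17 [-0.16], and luminal markers, 7 of 15 members higher and 2 lower (list mean 0.38 ± 0.02, adjusted p = 0.0140, adjusted p = 0.120 with an estimated correlation and 0.198 with median centring).

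Further lists higher in 2A than in WS8 at 96 h lost their call with an estimated correlation. They were immediate early genes, 11 of 20 members higher and 1 lower (list mean 0.49 ± 0.05, adjusted p = 0.00197, adjusted p = 0.158 with an estimated correlation), NF-kappaB genes, 6 of 27 members higher (list mean 0.33 ± 0.02, adjusted p = 0.00222, adjusted p = 0.0822 with an estimated correlation), and interferon-stimulated genes, 13 of 38 members higher and 1 lower (list mean 0.26 ± 0.03, adjusted p = 0.00610, adjusted p = 0.102 with an estimated correlation), in which OAS3 was lower by -2.76 ± 0.25 [0.06; probes: 0.03]. Hypoxia genes were higher too, 9 of 24 members higher and 3 lower (list mean 0.44 ± 0.03, adjusted p = 0.00793, adjusted p = 0.0822 with an estimated correlation), with EGLN3 at 2.36 ± 0.08, as were ATF6/XBP1 genes, 7 of 31 members higher and 2 lower (list mean 0.24 ± 0.04, adjusted p = 0.0111, adjusted p = 0.158 with an estimated correlation and 0.346 with median centring), CDK inhibitors, 5 of 14 members higher (list mean 0.37 ± 0.04, adjusted p = 0.0277, adjusted p = 0.0956 with an estimated correlation and 0.195 with median centring), and leukocyte markers, 2 of 12 members higher (list mean 0.38 ± 0.02, adjusted p = 0.0212, adjusted p = 0.158 with an estimated correlation). ESR1 was lower by -1.004 ± 0.10 [-0.47] and CASP4 higher by 0.65 ± 0.12 [0.36; probes: 0.50]. Between 2A and WS8, 537, 1586 and 2453 genes were higher and 1365, 2038 and 3134 lower at 6, 24 and 96 h, and the named genes of the fixed rule with a value on every array had a largest adjusted p of 7.31e-09, 2.36e-16 and 1.46e-41. Only 298 differed at 6 h less the 2 h difference. With median centring, 3951 and 1101 differed at 6 h and 4608 and 1380 at 24 h, and with the Feature Extraction log ratio 2190 and 2694 at 6 h.

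The difference between 5C and 2A asks where the 2 lines grown without estrogen part. At 6 h no list was called, and HMOX1 (-2.38 ± 0.18), PGR (-1.91 ± 0.13), AREG (-1.59 ± 0.15) and the carbonic anhydrase CA2 (-1.40 ± 0.11) were lower in 5C (6 and 6 arrays). ARL11, OR2W3, MORN5 and APOC2 were highest by the fixed rule, bounds in 2A, and over genes with a value on every array CBX2 (2.04 ± 0.45 [2 h: -0.305]), beta-catenin CTNNB1 (1.91 ± 0.17 [0.35; 2 h: 0.44]), PDZD9 (a bound in 2A) and ALYREF (1.64 ± 0.16 [2 h: 0.39]). At 24 h, PSCA (2.52 ± 0.11 [0.02]), MALAT1 (2.41 ± 0.35 [-0.50]), USP15 (2.34 ± 0.20 [-0.65; probes: 0.49]) and SYNPO2 (2.29 ± 0.09) were highest in 5C over genes with a value on every array, with CNGB1 (4.72 [-0.08; probes: 0.33]), C4orf36 (4.39) and the bounds ARL11 and APOC2 named by the fixed rule. S100A7 (a bound in 2A), PGR (-2.44 ± 0.13), AREG (-2.40 ± 0.15) and the interferon-induced HERC6 (-2.33 ± 0.09) were lower in 5C. TFF1 was higher by 1.86 ± 0.17. Interferon-stimulated genes were lower, 2 of 38 members higher and 18 lower (list mean -0.43 ± 0.02, adjusted p = 4.56e-09). OAS3 was higher by 1.72 ± 0.25 [-0.72; probes: -0.745]. NRF2 targets were lower, 6 of 21 members lower (list mean -0.40 ± 0.04, adjusted p = 1.48e-04), with HMOX1 at -1.47 ± 0.18, and hypoxia genes, 1 of 24 members higher and 5 lower (list mean -0.23 ± 0.01, adjusted p = 8.88e-04). Mitosis genes were lower, 10 of 32 members lower (list mean -0.45 ± 0.05, adjusted p = 4.79e-10, adjusted p = 0.0671 with an estimated correlation), as were cholesterol genes, 5 of 23 members lower (list mean -0.33 ± 0.03, adjusted p = 9.16e-05, adjusted p = 0.192 with an estimated correlation).

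At 96 h, KLHDC7B (4.02 ± 0.13), LTB (3.78 ± 0.13), SPTSSA (3.09 ± 0.11) and the membrane linker RDX (3.05 ± 0.10) were highest in 5C against 2A over genes with a value on every array, and by the fixed rule LINC01144 (4.98 [2 h: 0.50]), on 1 array of 2A, and DOCK4, STK32B and KLF17, bounds in 2A or 5C. S100A8 (-4.91 ± 0.11), SPRR3 (-4.62 ± 0.09), KRT6B (-4.18 ± 0.08) and S100A7 (-4.05 ± 0.12) were lower in 5C. Interferon-stimulated genes were higher in 5C, 16 of 38 members higher (list mean 0.65 ± 0.03, adjusted p = 6.96e-11, list mean turned to -0.08 with median centring), and NF-kappaB genes, 9 of 27 members higher (list mean 0.49 ± 0.06, adjusted p = 9.34e-04). Pro-apoptotic genes were higher, 5 of 15 members higher (list mean 0.59 ± 0.05, adjusted p = 0.00157, adjusted p = 0.394 with median centring and 0.0852 less the 2 h difference). BCL2L11 measured 1.45 ± 0.08 [-0.20; probes: 0.35] while BBC3 and HRK measured 1.67 ± 0.28 [0.21; 2 h: -1.02] and 1.24 ± 0.25 [0.41; 2 h: -0.59]. Caspase genes were higher, 7 of 16 members higher (list mean 0.37 ± 0.04, adjusted p = 0.0229, adjusted p = 0.109 with the Feature Extraction log ratio and 0.108 less the 2 h difference, list mean turned to -0.05 with median centring), with CASP4 at 1.06 ± 0.12 [median: 0.44], and death receptor and TNF family genes, 7 of 23 members higher (list mean 0.54 ± 0.06, adjusted p = 0.00943, adjusted p = 0.0764 with an estimated correlation and 0.326 with median centring). Ribosome biogenesis genes were higher, 3 of 27 members higher (list mean 0.25 ± 0.03, adjusted p = 0.00943, adjusted p = 0.210 with an estimated correlation and 0.115 less the 2 h difference, list mean turned to -0.32 with median centring). NRF2 targets were lower in 5C, 9 of 21 members lower (list mean -0.54 ± 0.02, adjusted p = 1.14e-06), with SRXN1 at -1.44 ± 0.07, and ATF6/XBP1 genes, 2 of 31 members higher and 11 lower (list mean -0.32 ± 0.05, adjusted p = 4.72e-05). HERPUD1 measured -1.54 ± 0.13 and HSPA5 -1.002 ± 0.13. Basal markers were lower, 1 of 17 members higher and 9 lower (list mean -0.48 ± 0.06, adjusted p = 1.31e-04). KRT6A measured -3.20 ± 0.08 and TP63 was higher by 2.60 ± 0.17 [0.01]. Replication genes were lower, 1 of 37 members higher and 7 lower (list mean -0.23 ± 0.08, adjusted p = 0.00568, adjusted p = 0.367 with an estimated correlation), as were cholesterol genes, 1 of 23 members higher and 6 lower (list mean -0.32 ± 0.05, adjusted p = 0.00157, adjusted p = 0.215 with an estimated correlation), and immediate early genes, 3 of 20 members higher and 8 lower (list mean -0.15 ± 0.06, adjusted p = 0.0401, adjusted p = 0.367 with an estimated correlation and 0.130 with the Feature Extraction log ratio), in which FOS was higher by 3.00 ± 0.14. TFF1 (2.16 ± 0.17) and GREB1 (2.79 ± 0.27 [0.06]) were higher in 5C. PGR was lower (-1.29 ± 0.13, but 0.07 with the Feature Extraction log ratio and the series matrix).

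Between 5C and 2A, 1348, 1884 and 2576 genes were higher and 313, 1057 and 1501 lower at 6, 24 and 96 h, and the named genes of the fixed rule with a value on every array had a largest adjusted p of 8.32e-17, 2.83e-28 and 3.24e-54. Only 338 differed at 6 h less the 2 h difference. With median centring, 1399, 1978 and 2188 were higher and 2384, 4721 and 5839 lower, and with the Feature Extraction log ratio 2425 and 1674 differed at 6 h and 4254 and 3781 at 96 h. The fibroblast list, the other foreign cell type, was called in no line and no difference, its mean lying between -0.04 and 0.24 in the lines and -0.04 and 0.18 in the differences.

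**Figure D3:**
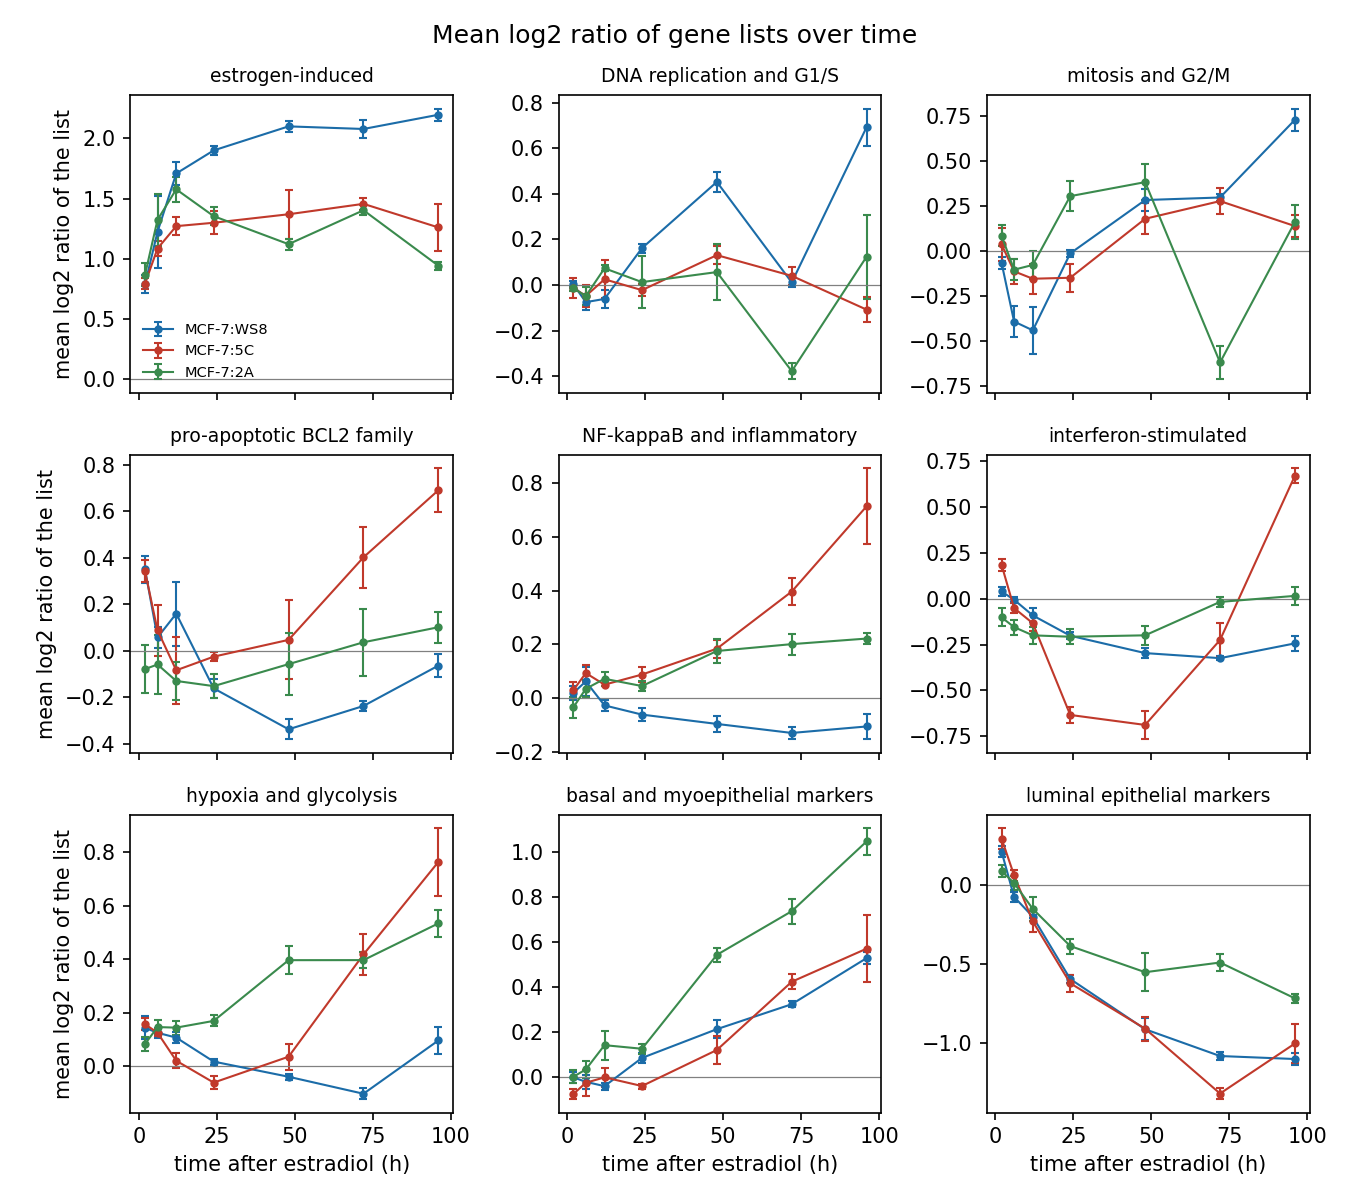
Mean log2 ratio of 9 gene lists (y axis) over hours of treatment (x axis), as mean ± SD of the array means of 4 to 6 arrays for each of the 3 lines. The interferon-stimulated list of 5C lay at -0.63 at 24 h and 0.67 at 96 h, the second turning to -0.11 with median centring.

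The time courses ask which genes changed between times within a line, where dye bias common to the slides of that line cancels. In WS8, 10624 genes changed. LINC00052 went from -0.40 ± 0.06 at 2 h to 4.62 ± 0.12 at 96 h, PMP22 from 0.03 ± 0.08 to -4.48 ± 0.11, CSTA from -0.04 ± 0.06 to -4.59 ± 0.14 and WNT11 from 0.06 ± 0.09 to -4.46 ± 0.12. In 5C, 8345 genes changed. CREB3L4, a membrane-bound transcription factor, went from 0.31 ± 0.10 to -2.70 ± 0.07, FHL2 from 0.20 ± 0.08 to 5.07 ± 0.23, the glycosyltransferase MGAT4A from -0.22 ± 0.14 to -3.08 ± 0.20 and the gluconeogenic enzyme FBP1 from -0.21 ± 0.04 to -3.34 ± 0.17. In 2A, 8146 genes changed, and the keratins KRT6B, KRT6A and KRT6C stayed between -0.38 and 0.09 until 24 h and reached 4.43 ± 0.18, 3.28 ± 0.15 and 3.01 ± 0.18 at 96 h, with SPRR3 at 4.65 ± 0.23. The largest adjusted p of these 12 genes was 3.98e-76. The slide as a fixed block gave 10767, 7822 and 8794 genes in WS8, 5C and 2A and the scan day as a random block 10630, 8316 and 8438; a slide holds at most 4 arrays, too few to fit times within 1 slide.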

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

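The tests of a spot defect and of repression by estradiol were chosen only after the result was seen. Arrays were compared within 167 groups of values, of which 30 held an array far from the others, where chance gives about 1 in 20.

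The spread of log2 ratios over genes stood apart on 1 array of 8 groups. It was high in 5C at 2 h (0.3562, the others 0.3024 to 0.322), 6 h (0.3428, others 0.2724 to 0.2969) and 12 h (0.3218, others 0.2878 to 0.2933). It was low in 5C at 48 h (0.2998, others 0.4229 to 0.4249), 72 h (0.432, others 0.4885 to 0.5109) and 96 h (0.3277, others 0.5317 to 0.5528), each time on replicate 3. It was low in 2A at 6 h (0.2136, others 0.3643 to 0.422) on replicate 6 and at 48 h (0.4398, others 0.4936 to 0.5253). Single genes had 1 array apart in WS8 at 24 h, namely TFF1 (2.42), CSTA (-3.19), ESR1 (-1.4) and CASP4 (0.46). In 5C these were DHRS3 at 6 h (1.58), GPER1 (-2.62), TM4SF1 (-3.24) and BCL2 (0.92) at 24 h, and PRSS23 (3.67), PDZK1 (2.98), EFEMP1 (-3.11), TFF1 (3.08), ESR1 (-1.83) and CASP4 (1.24) at 96 h. In 2A they were EGR3 (1.87), PGR (1.05) and HSPA5 (-0.31) at 6 h, NEFH (3.26), TFF1 (1.03), BCL2 (-0.24) and CASP4 (-0.12) at 24 h and S100A8 (5.27) at 96 h.

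Responses differed between lines by the test of the difference itself. Between 5C and WS8, 571, 1878 and 6376 genes differed at 6, 24 and 96 h, between 2A and WS8 1902, 3624 and 5587, and between 5C and 2A 1661, 2941 and 4077. For each of these 9 counts and 3 time courses, only the real one of 100 splits of the same arrays gave as many genes. The highest counts of the other splits were 183, 661 and 4200 for 5C and WS8, 1192, 1596 and 2742 for 2A and WS8, and 1126, 1207 and 2722 for 5C and 2A. For the time courses of WS8, 5C and 2A (10624, 8345 and 8146 genes) they were 4054, 3780 and 2200. Splits do not part line from scanner and slide, or line and time from pool.

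In 27 tests between lines a list was called and held with an estimated correlation. In 5C minus WS8 the mean of the ribosome biogenesis list was -0.26 at 6 h, -0.31 at 24 h and -0.41 at 96 h, and that of the interferon-stimulated list -0.43 at 24 h and 0.91 at 96 h. At 96 h the replication list stood at -0.8, CDK inhibitors at 0.59, pro-apoptotic genes at 0.75, death receptors and TNF family at 0.68, NF-kappaB at 0.82, p53 targets at 0.6 (turning sign with median centring) and hypoxia at 0.67. In 2A minus WS8 at 96 h, estrogen-induced genes stood at -1.25, NRF2 at 0.59, p53 targets at 0.7, ribosome biogenesis at -0.66 and basal markers at 0.52. In 5C minus 2A at 24 h, interferon-stimulated genes stood at -0.43, NRF2 at -0.4 and hypoxia at -0.23. At 96 h, the ATF6/XBP1 list stood at -0.32, pro-apoptotic genes at 0.59, NF-kappaB at 0.49, NRF2 at -0.54 and basal markers at -0.48, and caspases (0.37) and interferon-stimulated genes (0.65) turned sign with median centring.

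In 2A, 330 genes had spots left out as outliers on most arrays, ARL11, OR2W3, MORN5 and APOC2 among them. With those spots kept, the median log2 ratio of the set was -2.26 at 2 h and -2.00 at 96 h. Their ratio, 1.13, is what a defect of the spots on the 2A slides would give, which may account for the set and stays open. Repression by estradiol, which should deepen with time, is argued against by the 2 h median of -2.256. A damaged area of the slides is argued against by the median distance to the nearest other member, 5.831 spots. The closest 5% of 1000 random sets lay under 5.10. The set also enters the differences and r of 2A.

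At 2 h, WS8 called 835 genes higher and 101 lower, and 2A 243 and 1076, of which 165 were of the outlier set. Median centring gave 187 and 2856 in WS8 and the Feature Extraction log ratio 1759 and 1131, so the imbalance depends on the scale. A dye bias shared by all slides is argued against, since the genes higher in WS8 had a median of 0.03085 in 2A, though 0.76 in 5C, read on the same scanner as WS8. Their median in WS8 over 6 to 96 h was 0.4283 against 0.75 at 2 h, which dye bias of the slides of that line could give, but so would a lasting response to estradiol. The estrogen-induced list held 16 of 35 members among these genes (Fisher's exact p = 7.87e-16) and made up 1.916% of them; the bound set for that share was wrong, since 35 members can make up at most 4.19% of 835 genes. An early response to estradiol and dye bias of the line's slides cannot be told apart for these genes, as 1 dye orientation keeps both in the ratio.

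In 5C the interferon-stimulated list went from lower at 24 h to higher at 96 h, a shift of 1.30, or 0.99 with median centring, where the 96 h mean stays below 0. The estradiol channel (Cy3) rose by 2.06 between these times, 158.3% of the shift, and the vehicle channel (Cy5) by 0.76, which counts against it (-58.27%). Read as levels, the vehicle channel did not fall, as a change of the vehicle pool alone would ask. Scan day and slide differ between arrays and levels across slides carry them, so the hypothesis rests on these same data.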

How the results depend on the processing

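The alternatives that subtract the 2 h difference, keep outlier spots, ask for usable spots on 50% of the arrays, use the scan day or leave out arrays standing apart were chosen only after the result was seen. The direction of every called list and called named gene, and counts within 1.5 times, held under each alternative except as given here; the cause was not tested unless stated. As a percentage of the main count, the 33 counts lay between 94.8% and 134% without background correction and 99.9% and 100% without the filter on dim probes. They were 74.3% and 88.1% with the mean of the probes, 99.1% and 103% with the slide as a random block, 99.2% and 104% with the scan day, and 74.48% and 117.8% with array weights. They lay between 89.0% and 100% with only the groups compared, 99.8% and 116% with outlier spots kept, 80.2% and 99.6% with usable spots on 50% of arrays, and 98.2% and 119% without the 8 arrays standing apart. Leaving out 1 replicate number at a time gave 85.3% to 129%. Replicate numbers may pair the arrays weakly: residuals of the same number at different times had a median r of 0.039 over 331 pairs against -0.006 for other numbers, and 33 arrays were closest to their own number, where chance gives 19.7. With a replicate block, 926 genes were called in WS8 at 2 h and 10623, 8395 and 8493 in the time courses. Residuals of the same slide correlated at 0.0895 in the median, and the fitted correlation was 0.0304 for the slide and 0.0251 for the scan day. Weak signal limits genes whose channel is not well above background, which have only a bound. Of the 141 called lists, 68 lost their call with an estimated correlation, 39 with median centring (15 with the opposite sign) and 8 with the Feature Extraction log ratio, and at most 8 did so under each other alternative run. Gene calls were lost too: of 939 gene values, 161 lost their call with a 2-fold minimum, 71 with the mean of the probes, 60 with median centring and at most 9 under each other alternative but the subtractions, and 65 of 499 did so less the 2 h mean and 48 of 399 less the 2 h difference.

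The Feature Extraction log ratio, centred on the median of each array, called 2890, 3266, 7154, 7207, 8012, 7529 and 8649 genes in WS8 from 2 h to 96 h, 2873, 2478, 2223, 4345, 4244, 6321 and 8418 in 5C and 3194, 4535, 5390, 6923, 7328, 6963 and 7395 in 2A. It called 1630, 3954 and 10417 between 5C and WS8 at 6, 24 and 96 h, 4884, 6924 and 10330 between 2A and WS8, 4099, 5761 and 8035 between 5C and 2A, and 17373, 12705 and 13430 in the time courses of WS8, 5C and 2A. The series matrix, which holds the same ratios without that centring, called 2890, 3264, 7154, 7207, 8012, 7529 and 8682 in WS8, 2883, 2477, 2227, 4343, 4247, 6325 and 8410 in 5C and 3194, 4535, 5390, 6923, 7328, 6963 and 7395 in 2A. Between lines in the same order it called 1632, 3958 and 10467, 4882, 6924 and 10429 and 4106, 5759 and 8041, and 17488, 12712 and 13426 in the time courses. Under both, PGR turned to -0.365 in 2A minus WS8 at 24 h, and in 5C minus 2A at 96 h to 0.073 with the log ratio and 0.072 with the matrix.

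A 2-fold minimum, which calls fewer genes by construction, left 158, 157, 960, 1203, 1633, 1640 and 1777 in WS8, 325, 183, 247, 541, 783, 1415 and 1623 in 5C and 482, 542, 776, 1216, 1458, 1312 and 1227 in 2A. Between lines it left 77, 386 and 2355 for 5C and WS8, 601, 978 and 1807 for 2A and WS8, 640, 766 and 1411 for 5C and 2A, and 4056, 2912 and 2385 in the time courses.

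Median centring called 3043, 4441, 7802 and 6617 in WS8 at 2, 6, 12 and 24 h and 6569, 3499, 1922, 6360 and 9548 in 5C at 2, 6, 12, 24 and 96 h. It called 927 between 5C and WS8 at 6 h, 5052 and 5988 between 2A and WS8 at 6 and 24 h, and 3783, 6699 and 8027 between 5C and 2A. It turned TFF1 to -1.07 in 5C at 2 h and -0.116 in 5C minus WS8 at 96 h, HSPA5 to -0.784 in 5C at 96 h and PPAN to -0.025 in 5C minus 2A at 96 h. It turned HSPA8 to -0.045 and HSPH1 to -0.039 in 5C at 24 h, and HSPA4 to -0.016, HSPE1 to -0.18 and HSPB1 to -0.232 at 96 h. The mean of the probes turned BCL2 to 0.92 in WS8 and -0.282 in 2A at 96 h, -0.652 in 5C minus WS8 and -1.202 in 2A minus WS8, SEL1L to 0.124 and OAS3 to 0.034 in 2A minus WS8 at 96 h, and OAS3 to -0.745 in 5C minus 2A at 24 h, since probes of these genes disagree.

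Less the 2 h mean, 609 and 1910 genes were called in WS8 at 6 and 12 h, 388 and 2035 in 5C, 308 and 947 in 2A, and 2419 in 2A at 72 h. Subtraction also removes any estradiol response at 2 h. In WS8, MYC turned to -0.265, HMOX1 to -0.433 and IER3 to -0.851 at 6 h and LIG1 to -0.3 at 24 h. In 5C at 6 h, FOXC1 turned to -0.921, MYC to -0.354, EFNA1 to 0.102 and FOS to -0.056. In 2A, PDZD9 turned to 0.104, EFNA1 to 0.109, FOS to -0.273 and JUNB to 0.246 at 6 h, and ARL11 to 0.071 and APOC2 to 0.632 at 24 h. Less the difference at 2 h, 200, 298 and 338 genes differed at 6 h between 5C and WS8, 2A and WS8, and 5C and 2A. In 2A minus WS8, SGK1 turned to -0.245, LOC441722 to 0.109, BCL2 to 0.376, CASP4 to 0.057 and PPAN to 0.036 at 6 h, and ARL11 to 0.075, APOC2 to 0.631 and BCL2 to 0.878 at 24 h. In 5C minus 2A, CBX2 turned to -0.305, PDZD9 to -0.074 and BCL2 to -0.329 at 6 h, APOC2 to -0.506 and BCL2 to -0.773 at 24 h, and BBC3 to -1.016 and HRK to -0.588 at 96 h, and LIG1 turned to 0.115 in 5C minus WS8 at 24 h.

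By these subtractions, splits of higher and lower genes at 24 h were 787 and 1721 in 5C and 1818 and 2459 between 5C and 2A.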
